A study of Sus scrofa with 12 samples.

How the data were processed

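Total RNA of porcine primary trophoblast cells was sequenced from 12 libraries, 6 Control and 6 EVs, after isolation with a kit that keeps small RNA and library construction with a stranded kit that removes ribosomal RNA, per the labels' protocols. The deposited values are whole-number counts per Ensembl gene, not normalized, in a single table of 30477 genes. FastQC, Trimmomatic, STAR, featureCounts 2.0.3 and DESeq2 1.34.0 and the genome build Sscrofa11.1 are named per the submitters' processing notes. The annotation release, the strand setting of the counting and the read filters are not given in the sources used here. Reads of overlapping genes on opposite strands can therefore not be told apart with certainty, and how reads shared between related genes were assigned is not known.

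Most nonzero deposited counts were even: odd numbers made up 31.0 to 33.9% of them per library. This bears on counting error, since an effective count could be lower than the deposited count. The counts were analysed as deposited, and halved counts were tried as an alternative. Libraries held 22762592 to 27769337 counts, which puts 3 counts at 0.108 to 0.132 CPM; 9740 genes had no count in any library. Pairs of libraries within a group differed by 26.5 to 490.9 times the chi-square expected from counting noise per degree of freedom. The Control and EVs libraries of an animal differed by 16.3 to 151.3 times, so no library appeared as a copy of another. The lowest value in each group joined animals 3 and 4, at 28.2 in Control and 26.5 in EVs. Their own Control and EVs pairs stood higher, at 151.3 in animal 3 and 68.9 in animal 4. Tests over animals treat animals 3 and 4 as independent, which was not tested.

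Groups and animals were taken from the labels, which give each library a treatment, a replicate number and an animal code shared by 1 Control and 1 EVs library. The labels' protocols state that vesicles and cells of a treatment came from the same animal. The replicate number was therefore a block in the design. As a check, the deviations of the Control and EVs libraries of an animal from their group means correlated across genes at 0.363 to 0.590 in the 6 animals. In animal 3 the correlation was 0.410 for its own pair and 0.436 with a library of animal 4; in the other 5 animals the own pair had the highest value. All choices of design, tests, gene lists and named genes were made before the data were examined, apart from those stated as later.

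Genes were kept with filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 13450, and scaled with TMM factors. Changes were tested with edgeR's quasi-likelihood test (robust dispersion and robust fit) with the animal as a block and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The SE of an edgeR log2 fold change was its size divided by the square root of its F statistic. CPM values are TMM scaled and are given as mean ± SD over the 6 animals. Symbols came from a table of gene names that matched 14864 of the 30477 IDs, which hold 87.5% of counts. Coordinates came from NCBI RefSeq genes of Sscrofa11.1 by unique symbol; SAMD9, CCN1 and UQCRQ had no such match.

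The 36 gene lists (968 members, 848 matched) were fixed by symbol and tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the same design and a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the 36 lists. Some genes stand in more than 1 list. Depth and composition were tested with an exact sign-flip permutation test over the 6 animals, two-sided, with 64 flips. Variance was divided by sums of squares over all genes tested. Genes differing between animals were tested with the F test of the animal terms in the edgeR fit.

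Named genes followed a rule. Up to 10 genes per direction past the threshold, with a gene symbol, a mean log2 CPM of at least 1 and the same sign in 6 animals, were to be named; as fewer than 5 passed, the 5 with the smallest p that met the other conditions were named per direction. Each list gave up to 3 members past the threshold, or else the member with the smallest p. KRT8, KRT18, GATA3, CDX2, VIM, EPCAM and PTPRC were named whatever their p.

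Alternatives were no block, other normalizations, other filters, other thresholds, DESeq2 1.42.0, limma-voom, a fit without robust estimation, library size as a covariate and each animal left out in turn. The fits were tested on simulated data with the real means and library sizes for EVs against Control. Of 200 changed genes, edgeR recovered 25.8% at an absolute log2 fold change of 0.5, 56.1% at 1 and 77.9% at 2, with 4 false calls among 13250 unchanged genes. DESeq2 recovered 43.9%, 75.8% and 86.8%, with 32 false calls. With no gene changed, edgeR made 0 and DESeq2 13 calls over 13450 genes. A list of 33 genes shifted by 0.5 was found by camera with the preset correlation (adjusted p = 3.52e-13). Camera with the estimated correlation also found it (adjusted p = 0.0107), and no other list was called in the simulations. Of these 33 genes, edgeR called 0 and DESeq2 called 4 (12.1%). The absence of edgeR calls therefore does not exclude a shift of this size confined to a list. The simulated genes were drawn independently of each other, whereas the estimated correlation was 0.11 in the real interferon list and 0.21 in the endoderm list. The simulations therefore cannot show how often camera with the preset correlation calls lists of correlated genes by chance. Figures were drawn with matplotlib. No reads were analysed here.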

Results

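Primary trophoblast cells, the outer epithelium of the pig conceptus that faces the uterine lining, were isolated on day 16 of pregnancy and exposed in culture to extracellular vesicles (EVs), membrane-bound particles that cells release. The vesicles had been collected from the uterus of the same female. Exposure to 2% EVs lasted 6 h in serum-free medium and was followed by 18 h in medium with 10% newborn calf serum. What the Control cells received in place of the vesicles is not stated in the labels. Each of 6 animals gave 1 Control and 1 EVs library of ribosome-depleted total RNA, so that there were 6 libraries per group and 12 in all. Total counts per library ran from 22762592 in the Control library of animal 3 to 27769337 in the Control library of animal 6. Between 14562 and 16478 genes had at least 1 count in a library, and 13450 genes had enough counts to be tested. A gene at 3 counts stood at 0.108 to 0.132 CPM (counts scaled to a common library total), depending on the library. These floors cover counting error only. Total counts did not differ between the groups by more than the spread between animals, with higher values in the EVs library of 4 of 6 animals (exact sign-flip permutation test, two-sided, p = 0.219; the smallest p it can give is 0.03125).

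The comparison of EVs with Control within each animal addressed the effect of uterine vesicles on trophoblast gene expression. As lists, in camera with a preset correlation between genes, genes of the interferon response rose in the EVs libraries, while genes of cholesterol synthesis and uptake and markers of the extraembryonic endoderm, the inner layer of the conceptus membranes, fell. None of these 3 lists passed when the correlation was estimated (adjusted p = 0.656 each), and the endoderm list was also lost without the block. No single gene passed the threshold in edgeR's quasi-likelihood test with the animal as a block: 0 genes were higher and 0 lower at an adjusted p under 0.05, with 457 higher and 510 lower at an unadjusted p under 0.05 where chance alone gives 672.5 in all. The smallest adjusted p was 0.375. DESeq2 with the animal as a block called 21 genes higher and 19 lower, and limma-voom with the same block called 0 and 0. Without the block, edgeR called 0 and 0 and DESeq2 called 1 and 1. Over the 13450 genes, 725 (5.39%) moved the same way in all 6 animals, 407 up and 318 down, where 3.125% would do so by chance on average. Genes are not independent of each other, and how far this share varies by chance was not tested.

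The interferon-response list holds genes that cells switch on after sensing interferon or viral RNA. Of its 33 members tested, 28 were higher and 5 lower with EVs, with a median log2 fold change of 0.52. The median difference of the list was above 0 in 6 of 6 animals, from 0.11 in animal 5 to 0.97 in animal 1 (0.53 ± 0.29, SD, n = 6). The list passed limma's camera test with a preset correlation between genes of 0.01 (adjusted p = 1.04e-08 over 36 lists). It did not pass with an estimated correlation (adjusted p = 0.656) or in limma's fry test for movement on balance in a single direction (adjusted p = 0.163), while fry's test for change in either direction gave an adjusted p of 0.0413. No member passed edgeR over all genes, and 11 passed when adjusted over the list alone. SAMD9, an interferon-induced antiviral factor, had the smallest p in the list, at 39.8 ± 27.6 CPM in Control and 60.2 ± 35.0 CPM in EVs (SD, n = 6), a log2 fold change of 0.74 (SE 0.15) that was positive in 6 of 6 animals. Further members are named after their values were seen. ISG15, a ubiquitin-like modifier, stood at 15.1 ± 8.08 CPM in Control and 39.1 ± 23.8 CPM in EVs, with a log2 fold change of 1.28 (SE 0.32) and higher values in 5 of 6 animals. IFI6 stood at 13.1 ± 9.66 and 38.8 ± 29.9 CPM, a log2 fold change of 1.71 (SE 0.51). The guanylate-binding protein gene GBP1 had a log2 fold change of 0.93 (SE 0.21), PARP14 of 1.11 (SE 0.24) and the antiviral GTPase gene MX1 of 0.76 (SE 0.29). The transcription factor gene STAT1 was the most abundant member, at 137 ± 94.3 CPM in Control and 166 ± 96.7 CPM in EVs. EIF2AK2 and IFIT5 differed little in their means, at 84.9 ± 26.2 and 84.8 ± 22.4 CPM and at 67.1 ± 20.4 and 67.1 ± 16.9 CPM. CXCL10, near 1 CPM, had the largest fall in the list, a log2 fold change of -0.45 (SE 0.62). The leukocyte marker list did not pass in the same libraries (5 of 8 tested members higher, adjusted p = 0.938 by camera). The extraembryonic endoderm list was lower in camera with the preset correlation, but its median difference was above 0 in animal 3 (0.24).

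**Figure D1:**
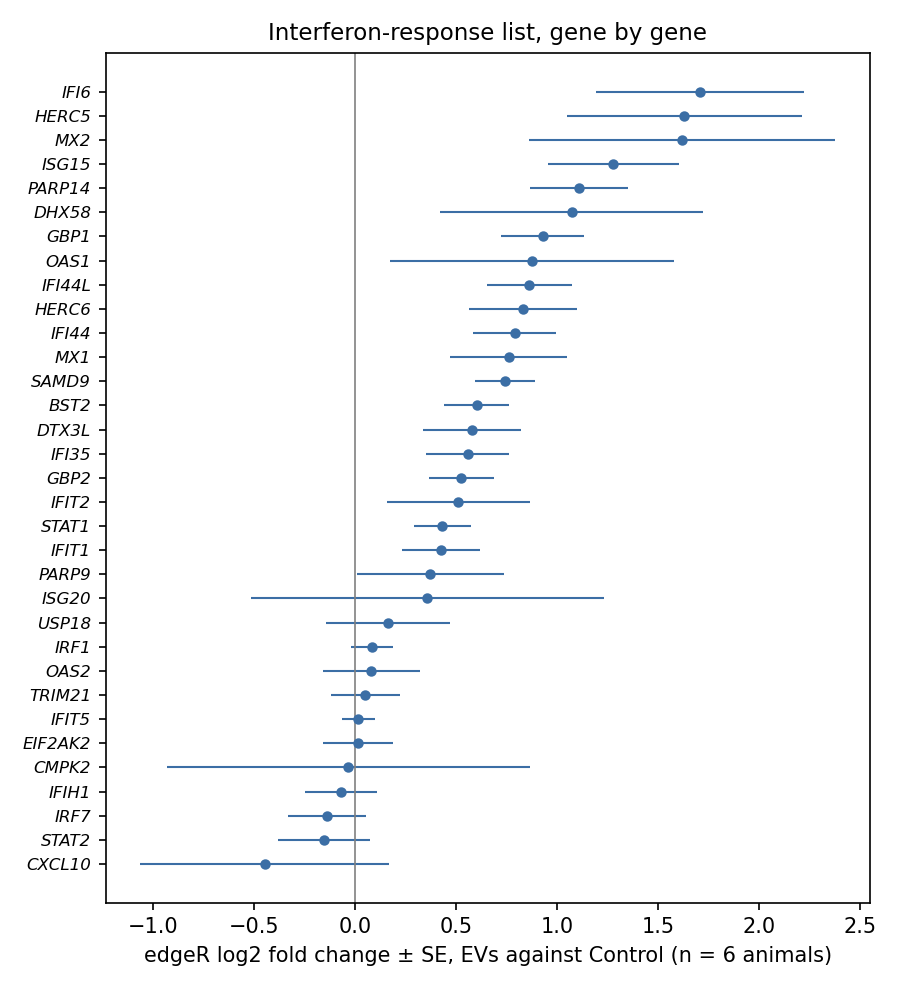
Each point is the edgeR log2 fold change of a gene of the interferon-response list, EVs against Control over 6 animals, and each bar is ± 1 SE; genes are ordered by fold change. Of the 33 genes, 28 lie above 0, from IFI6 at 1.71 downward, and CXCL10 is lowest at -0.45.

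Other immune lists had smaller median log2 fold changes than the interferon-response list, a difference between lists that was not tested. In animal 2 the median difference was larger for antigen presentation (0.95) than for the interferon response (0.66). In the antigen-presentation list, 7 of 10 tested members were higher, with a median log2 fold change of 0.29 and an adjusted p of 0.238 by camera. Its member TAP1, a subunit of the peptide transporter for class I presentation, stood at 67.2 ± 45.7 CPM in Control and 88.8 ± 52.2 CPM in EVs (log2 fold change 0.54, SE 0.13, positive in 6 of 6 animals), and was the 1 member that passed when adjusted over the list alone. In the list of NF-kB targets and inflammatory cytokines, 11 of 20 were higher (adjusted p = 0.238). The neutrophil chemokine gene CXCL8 had its smallest p, with a log2 fold change of 0.53 (SE 0.19). Among conceptus cytokines and growth factors, 9 of 15 were higher (adjusted p = 0.238), and TGFB3 had a log2 fold change of 0.25 (SE 0.12). Immediate early genes had 13 of 22 higher (adjusted p = 0.750), with KLF6 at a log2 fold change of 0.25 (SE 0.09).

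The list of cholesterol synthesis and uptake was lower with EVs in camera with the preset correlation only. Of 22 members tested, 19 were lower and 3 higher, with a median log2 fold change of -0.14. The median difference of the list was below 0 in 6 of 6 animals (-0.17 ± 0.09, SD, n = 6). The list passed camera with the preset correlation (adjusted p = 2.48e-04) and did not pass with an estimated correlation (adjusted p = 0.656) or in fry (adjusted p = 0.166; 0.0234 for change in either direction). The members adjusted over the list alone gave 2 genes past the threshold. DHCR24, which encodes the reductase of the sterol side chain, stood at 62.2 ± 20.02 CPM in Control and 44.3 ± 17.4 CPM in EVs (log2 fold change -0.54, SE 0.10), lower in 6 of 6 animals. The other was IDI1, an isomerase of the isoprenoid pathway, with a log2 fold change of -0.34 (SE 0.08). Named after their values were seen, HMGCS1 had a log2 fold change of -0.22 (SE 0.07), the rate-limiting enzyme gene HMGCR of -0.16 (SE 0.09) and the lipoprotein receptor gene LDLR of -0.15 (SE 0.08). The extraembryonic endoderm list, which includes apolipoprotein genes, was also lower in camera with the preset correlation, but its median difference was above 0 in animal 3 (0.24). In the list of fatty acid and lipid droplet metabolism, 16 of 25 members were lower (adjusted p = 0.631 by camera). Its member SREBF1, a transcription factor of lipid synthesis, had a log2 fold change of -0.64 (SE 0.21).

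In the list of extraembryonic endoderm markers, 13 of 16 tested members were lower, with a median log2 fold change of -0.38. The list's median difference was above 0 in 1 of 6 animals, from -0.84 in animal 1 to 0.24 in animal 3 (-0.26 ± 0.38, SD, n = 6). It passed camera (adjusted p = 0.00454), did not pass with an estimated correlation (adjusted p = 0.656) or in fry (adjusted p = 0.390), and no member passed when adjusted over the list alone. APOA2, an apolipoprotein gene, stood at 145 ± 151 CPM in Control and 88.9 ± 82.4 CPM in EVs (log2 fold change -0.51, SE 0.14), lower in 5 of 6 animals. The members of this list took 0.876 ± 0.683% of counts in Control and 0.622 ± 0.363% in EVs (SD, n = 6), a difference that did not pass the exact sign-flip permutation test (two-sided, p = 0.0938; adjusted p = 0.656 over 14 measures). Animal 1 went from 1.98 to 1.13%, and without it the mean difference was -0.135 percentage points in place of -0.254. The call was lost in camera without animal 1 (adjusted p = 0.0617) and without animal 6 (adjusted p = 0.0504), and without the animal as a block (adjusted p = 0.249).

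**Figure D2:**
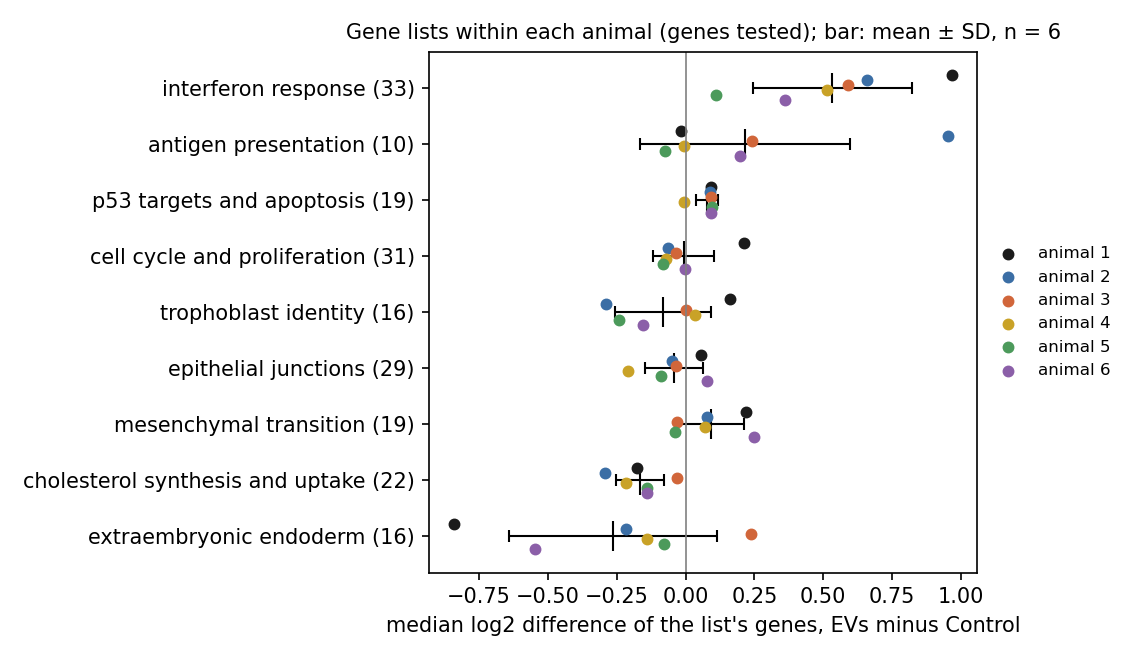
Points give the median log2 difference of a gene list, EVs minus Control, in each of 6 animals, for 9 of the 36 lists; the vertical tick and bar give the mean ± SD over animals, and the number of genes tested stands in parentheses. The interferon-response medians lie above 0 in 6 of 6 animals and the cholesterol medians below 0 in 6 of 6. The medians of endothelium markers, not drawn, were also below 0 in 6 of 6, and that list did not pass camera (adjusted p = 0.483).

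Of the genes with a symbol, those with the smallest p and the same direction in all 6 animals are given as values that did not pass edgeR over all genes; each passed DESeq2 with the animal as a block. TSPAN12, which encodes a tetraspanin of the Norrin receptor complex (chromosome 18, 26046645 to 26112924, Sscrofa11.1), stood at 27.1 ± 15.4 CPM in Control and 43.4 ± 26.5 CPM in EVs (SD, n = 6). Its log2 fold change was 0.66 (SE 0.09), with 0.57 to 0.83 in single animals. The adjusted p was 0.375 in edgeR and 6.37e-06 in DESeq2. Genes were chosen here for a small p and the same direction in all 6 animals, so a narrow range follows in part from the choice. The DESeq2 calls come from the same counts. Of the 32 groupings of the labels within animals, 6 gave as many DESeq2 calls, the real grouping among them. JAM3, a junctional adhesion molecule gene (chromosome 9, 60629245 to 60738979), had a log2 fold change of 0.43 (SE 0.09). OSBPL8, a lipid transfer protein gene (chromosome 5, 39568136 to 39744655), had 0.35 (SE 0.07), and the myosin chaperone gene UNC45B (chromosome 12, 39997254 to 40031368) had 0.65 (SE 0.14). SAMD9 was the fifth gene on the higher side. On the lower side, the receptor phosphatase gene PTPRF (chromosome 6, 167656674 to 167743750) stood at 253 ± 54.6 CPM in Control and 192 ± 46.1 CPM in EVs, a log2 fold change of -0.40 (SE 0.07). YPEL3 (chromosome 3, 18277999 to 18281342) had a log2 fold change of -0.62 (SE 0.11). GPC3, a glypican of the cell surface (chromosome X, 109536495 to 109973605), had -0.65 (SE 0.12), and MTSS1, which encodes a membrane-bending actin regulator (chromosome 4, 14933290 to 15103256), had -0.65 (SE 0.13). DHCR24 (chromosome 6, 157483794 to 157519060) completed the list. Apart from TSPAN12, all of them had an edgeR adjusted p of 0.608.

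**Figure D3:**
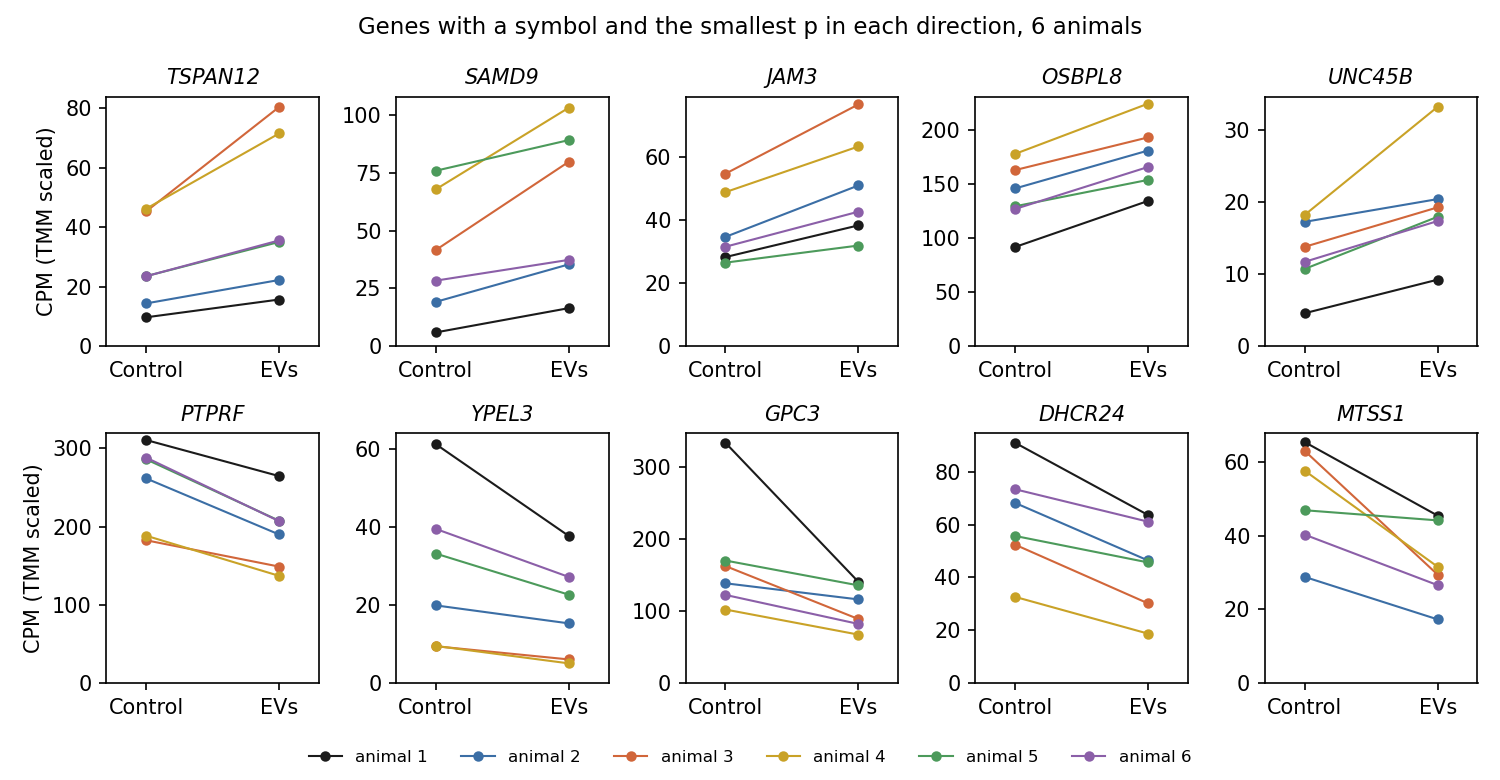
Lines join the Control and EVs values of the same animal, in CPM after TMM scaling, for the 5 genes with the smallest p among those with a symbol and higher in all 6 animals (top) and the 5 among those with a symbol and lower in all 6 (bottom). Each vertical axis starts at 0; TSPAN12 goes from a mean of 27.1 to 43.4 CPM and PTPRF from 253 to 192 CPM.

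Trophoblast identity genes did not pass as a list: 5 of 16 tested members were higher (median log2 fold change -0.06, adjusted p = 0.380 by camera). The keratin genes KRT8 and KRT18, markers of simple epithelium, were abundant in both groups. KRT8 stood at 9681 ± 3856 CPM in Control and 8908 ± 2870 CPM in EVs, and KRT18 at 3935 ± 2081 and 3521 ± 1578 CPM (SD, n = 6). CDX2, a trophectoderm transcription factor, stood at 6.15 ± 1.81 and 6.32 ± 1.80 CPM, and GATA3 at 3.96 ± 1.90 and 2.21 ± 0.954 CPM. The epithelial adhesion gene EPCAM stood at 299 ± 141 and 261 ± 116 CPM. OVOL1, a transcription factor of trophoblast differentiation, had a log2 fold change of -1.10 (SE 0.43) and was lower in 6 of 6 animals. Genes of conceptus steroid and prostaglandin synthesis had 12 of 14 members lower (adjusted p = 0.479), with PTGS1 at a log2 fold change of 0.23 (SE 0.12). The leukocyte gene PTPRC had too few counts to be tested.

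Among lists of cell shape and adhesion, none passed camera. In the epithelial-junction list, 21 of 29 members were lower (adjusted p = 0.109), and RAB25, a trafficking GTPase of epithelial cells, had a log2 fold change of -0.999 (SE 0.28). In the mesenchymal-transition list, 8 of 19 were higher (adjusted p = 0.794), the median log2 fold change was -0.06 and the mean 0.02, and 3 members passed when adjusted over the list alone. The actin gene ACTA2 had a log2 fold change of 0.32 (SE 0.08), and the intermediate filament gene VIM stood at 1379 ± 945 CPM in Control and 1743 ± 1148 CPM in EVs, higher in 6 of 6 animals. The extracellular matrix list had 19 of 29 lower (adjusted p = 0.109), with the basement membrane gene NID1 at -0.34 (SE 0.11). Integrins and focal adhesion had 15 of 32 higher (adjusted p = 0.999), with the kinase gene SRC at -0.30 (SE 0.08). Proteases and inhibitors of matrix remodelling had 15 of 25 higher (adjusted p = 0.380), with the plasminogen activator gene PLAT at 0.52 (SE 0.17). Cytoskeleton and migration had 16 of 29 higher (adjusted p = 0.380), with ARPC5 at 0.24 (SE 0.08), and TGF-beta and YAP targets had 11 of 25 higher (adjusted p = 0.962), with CCN1 at 0.29 (SE 0.12).

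Growth, signalling and stress lists did not pass camera either. Cell cycle and proliferation had 16 of 31 members higher (adjusted p = 0.999), with the replication licensing gene CDT1 at a log2 fold change of -0.43 (SE 0.12). The p53 and apoptosis list had 13 of 19 higher (adjusted p = 0.238), with CASP8 at 0.33 (SE 0.12). Angiogenic factors and receptors had 15 of 22 lower (adjusted p = 0.238), with PDGFA at -0.31 (SE 0.12), and wnt and notch signalling had 12 of 27 higher (adjusted p = 0.999), with LFNG at 0.43 (SE 0.14). The unfolded protein and amino acid response had 15 of 26 lower (adjusted p = 0.445), and its serine synthesis gene PSAT1, at 122 ± 80.6 CPM in Control and 76.8 ± 33.7 CPM in EVs, was the 1 member that passed when adjusted over the list alone. Heat shock and oxidative stress had 10 of 19 higher (adjusted p = 0.999), with PRDX1 at 0.18 (SE 0.08). Hypoxia and glycolysis had 15 of 23 higher (adjusted p = 0.174), with HK1 at 0.27 (SE 0.09).

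Vesicle and organelle lists did not pass camera with the animal as a block. In the list of vesicle biogenesis and trafficking, 25 of 39 members were higher (adjusted p = 0.648 by camera), with RAB11B at a log2 fold change of -0.49 (SE 0.19). Endocytosis and lysosome had 21 of 33 higher (adjusted p = 0.545), with EPN1 at -0.28 (SE 0.09). Oxidative phosphorylation had 17 of 26 higher in fitted fold change (adjusted p = 0.759), with UQCRQ at -0.15 (SE 0.09). Its animal median was above 0 in 2 of 6 animals, 3 and 4. Ribosomal protein genes had 32 of 34 higher with a median log2 fold change of 0.06 (adjusted p = 0.109, 0.0422 with no block and 0.967 with an estimated correlation) and an animal median above 0 in 2 of 6 animals, with RPL38 at 0.17 (SE 0.10). The 13 mitochondrially encoded genes were all lower in fitted fold change (adjusted p = 0.206), with a median log2 fold change of -0.13 and an animal median above 0 in 3 of 6 animals. The mitochondrial gene ND2 had -0.76 (SE 0.53).

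Markers of other cell types were measured in the same libraries. Erythroid genes had 4 of 4 tested members higher, with a median log2 fold change of 1.10 (adjusted p = 0.0509 by camera, 0.0467 with DESeq2 size factors and 0.656 with an estimated correlation). Animals 3 and 4 carried this, with list medians of 2.34 and 1.74 against -0.20 to 0.49 in the other 4. Levels were low: ALAS2, a heme synthesis enzyme of red cells, stood at 0.366 ± 0.241 CPM in Control and 1.74 ± 2.16 CPM in EVs. Fibroblast and stroma had 4 of 13 higher (adjusted p = 0.483), with DCN at a log2 fold change of -0.43 (SE 0.14). Endothelium had 2 of 10 higher (adjusted p = 0.483), with a median log2 fold change of -0.23 and an animal median below 0 in 6 of 6 animals. PECAM1, at 0.48 (SE 0.15), was among the 2 that were higher. The share of counts in endothelium markers went the other way, at 0.0156% in Control and 0.0169% in EVs, higher in 5 of 6 animals. Leukocyte markers took 0.00342% of counts in Control and 0.00344% in EVs, and ITGAM had a log2 fold change of -0.29 (SE 0.18). Extraembryonic mesoderm and smooth muscle had 6 of 13 higher (adjusted p = 0.836), with HAND1 at -0.69 (SE 0.37). Epiblast had 3 of 5 higher (adjusted p = 0.999), with LIN28B at -0.19 (SE 0.12), and uterine epithelium had 1 of 3 higher (adjusted p = 0.999), with CFTR at 0.66 (SE 0.62).

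More of the variation went with the animal than with the treatment. The animal accounted for 69.0% of the summed variance of log2 CPM, the treatment for 5.89% and the remainder for 25.2%. Libraries with neither an animal nor a treatment effect would give 45.5%, 9.09% and 45.5%. As the animal took more than that, 9.09% is not a reference for the treatment's share. The treatment had 1 degree of freedom and the remainder 5, and the shares were not tested. In edgeR's quasi-likelihood test of the animal terms, 3080 of 13450 genes (22.9%) differed between animals at an adjusted p under 0.05. The first principal component held 38.8% of the variance and set animals 3 and 4 apart from the other 4 in both groups. The genes given here were named after their values were seen. Fibronectin (FN1) averaged 32011 and 33528 CPM in animals 3 and 4 and 9958 to 13854 CPM in the other 4. The smooth muscle actin gene ACTA2 averaged 3629 and 3567 CPM in animals 3 and 4 and 301 to 844 CPM in the others, and the matrix glycoprotein gene THBS1 ranged 36.6-fold over all 6. In the other direction, the apolipoprotein gene APOA1 averaged 11748 CPM in animal 1 and 1057 CPM in animal 3, and KRT8 13684 and 5587 CPM. IFNG, the type II interferon that pig conceptuses secrete, ranged from 0.548 CPM in animal 2 to 137 CPM in animal 6. The stroma list lay 1.52 and 1.33 log2 units above the mean of all animals in animals 3 and 4, and the extraembryonic endoderm list lay at -0.97 and -0.93 there.

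**Figure D4:**
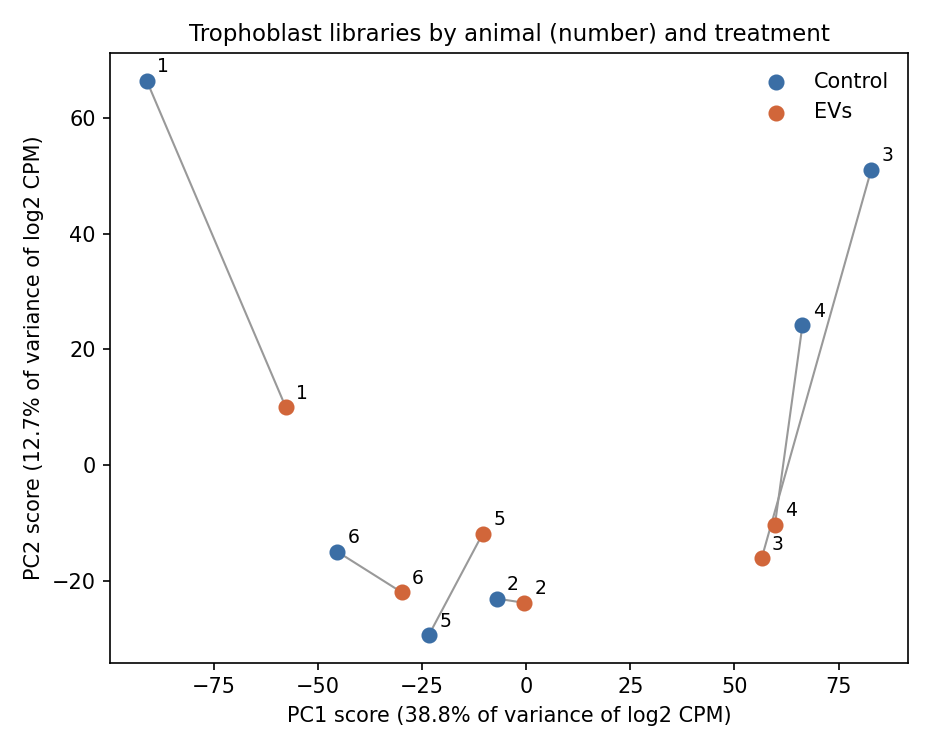
Scores of the 12 libraries on the first and second principal components of log2 CPM; the number at each point is the animal, the colour is the treatment and a line joins the Control and EVs libraries of an animal. The libraries of animals 3 and 4 lie at the right and those of animal 1 at the left, in both groups.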

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

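In 201 groups of 6 values tested, 6 had a library whose gap to its nearest neighbour exceeded 0.625 of the group's range; chance flags about 1 in 20 groups, or 10.05 here. In Control, animal 1 stood apart for GPC3 at 333.8 CPM (others 102 to 170 CPM) and for NID1 at 778 CPM (others 299.8 to 435 CPM). The Control library of animal 4 stood apart for PECAM1 at 113 CPM (others 35.9 to 63.7 CPM), and that of animal 2 for CDX2 at 9.75 CPM (others 4.97 to 5.91 CPM). Among EVs libraries, animal 5 stood apart for ND2 at 27.4 CPM (others 8.79 to 15.2 CPM), and animal 2 for the median of the hypoxia and glycolysis list, at -0.16 log2 units from the mean of the libraries (others 0.01 to 0.10).

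The regroupings of samples other than that of the smallest p over all lists, the leukocyte test, the uterine test, the test of distances on thinned counts and the mixed Control libraries were chosen after the results were seen. The regrouping of the smallest p, the thinned interferon test, the mixing fraction and the test of even counts were set out before. Regroupings exchanged the labels within animals, which gives 32 splits that part all 6 pairs. They treat animals 3 and 4, whose libraries were the closest pair within each group, as independent. EdgeR called 0 genes, a count that all 32 splits reach whatever the data and that decides nothing; the most in another split was 1. In the other gene counts chance could not be excluded. At an unadjusted p under 0.05 edgeR gave 967 genes, 7 of the 32 splits gave as many, and the highest other had 1787. DESeq2 with the animal as a block called 40 genes, 6 of the 32 splits called as many, and the highest other, 189, exchanged the labels of animals 3 and 4. In that split the smallest camera p of any list was 1.47e-09, for oxidative phosphorylation. The medians of this list, EVs minus Control, were 0.37 and 0.22 in animals 3 and 4 and -0.14 to -0.06 in the others. Animals 3 and 4 thus moved in the opposite direction for this list. Whether this accounts for the high gene count was not tested. The 3 lists past camera were matched or exceeded in number by 20 of the 32 splits, with 12 lists in the highest other.

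The first pattern is the rise of the interferon-response list with EVs. Its camera p of 2.89e-10 was reached by 1 of the 32 splits, the real one, which is the smallest share they can give. The next smallest camera p for this list in a split was 3.71e-07. In a different split the ribosomal protein list gave 4.95e-10, the next smallest camera p for any of the 36 lists. The splits argue against chance only narrowly, and only for camera with the preset correlation (adjusted p = 0.656 with an estimated one). The exact sign-flip permutation test of the list's animal medians gave p = 0.03125, the smallest it can give. Its adjusted p over the 36 lists was 0.375, so chance stays open. Thinning every library to the smallest total left the list at a median log2 fold change of 0.55 against 0.52 before. Fold changes are already scaled by library total, so this outcome was largely fixed in advance and does not decide on depth. The leukocyte marker share had a mean log2 change of -0.000802 (95% interval -0.33 to 0.33), below the 0.43 of the summed interferon list. This argues only against a rise of leukocytes in proportion to the interferon list. A smaller rise stays open, since the markers took 0.00342% of counts in Control. No library of leukocytes gives their ratio of markers to interferon genes. Leukocyte genes such as LCP1 and AIF1 stood at 2.66 and 8.77 CPM in Control. Whole uterine epithelial cells stay open: the 11 of 14 uterine markers under 1 CPM in Control changed by -0.764 CPM in sum (95% interval -1.86 to 0.331) while the interferon list rose by 219 CPM, but these markers lie near the floor, 2 have no count, and no library of uterine cells gives the level they would need. Candidate explanations that also stay open are RNA held in the vesicles, and a response of the trophoblast cells to the vesicles or to what is prepared with them, which the design cannot part from other differences in handling.

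The second pattern is that libraries of different animals were more alike with EVs. Their mean distance was 0.985 log2 units (root mean square) in EVs and 1.17 in Control, a shrinkage of 15.5%; the difference of 0.18 was reached by 1 of the 32 splits, the real one, but the next gave 0.179 and other settings let another split exceed it, so chance stays open. Thinning left the difference at -0.174 (EVs minus Control), so uneven depth does not account for it. Mixing of RNA between animals stays open: 15 genes from 4 animals, near 0 in the animal's own Control and high in the others, reached a median fraction of 0.0404 of the others' level in the EVs library (95% bootstrap interval over genes 0.0186 to 0.0955), and the limit of 0.155 set before was wrong, being a share of log2 distance, since Control libraries mixed at these fractions had distances shorter by 10.9% (5.73 to 21.2%). Both ranges come from resampled genes and do not measure the spread between animals. The genes were chosen for a value near 0 in Control, so a higher value with EVs follows in part from the choice. The reverse choice, of genes near 0 with EVs, was not tested. A convergence of the cultures during exposure, or animals 1, 3 and 4 having unusual Control cultures, may each account for the larger likeness, and both stay open.

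The third pattern is the excess of even counts. Odd numbers made up 10.0 to 13.3% of the counts from 1 to 20 per library, and 46.1 to 49.3% of those over 1000, where 45% was the lower limit set for mates counted singly. Both mates of a read pair having been counted as separate reads, with some mates lost, is consistent with this, whereas counts doubled at every level would have stayed even; the strand and pair settings of the counting are not given in the sources used here. No biological explanation was tested.

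The other list calls had different outcomes over the splits. The camera p of the cholesterol list, 1.38e-05, was reached by 1 of the 32 splits, the real one, with 1.54e-05 in the next; as the list was chosen from 36, 20 of the 32 splits called as many lists and the adjusted p was 0.656 with an estimated correlation, chance stays open for it. The smallest p over all 36 lists was reached by 1 of the 32 splits, the real one, as given above. For the extraembryonic endoderm list chance could not be excluded: its camera p of 3.78e-04 was reached by 5 of the 32 splits, and the smallest of the others was 4.18e-06.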

How the results depend on the processing

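Chosen after the data were seen were the runs without animals 3 and 4, those on halved counts and all those on distances between libraries. Genes past the edgeR threshold stayed at 0 in both directions with no replicate block, other scalings, filters and thresholds, limma-voom, library size as a covariate, halved counts and without each animal in turn (0 to 0). DESeq2 with the animal as a block called 21 higher and 19 lower (16 and 15 on halved counts), and DESeq2 with no replicate block 1 and 1. Without animals 3 and 4, edgeR called 3 genes lower and 0 higher.

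Lists past camera, 1 higher and 2 lower, became 0 and 0 with an estimated correlation and with fry, 2 and 1 with no replicate block, 2 higher with DESeq2 size factors, and 2 and 5 without animals 3 and 4. Without each animal in turn they ran from 1 to 2 higher and from 1 to 4 lower. The adjusted p for the interferon, cholesterol and endoderm lists was 0.656 each with an estimated correlation, and 0.163, 0.166 and 0.390 with fry. The endoderm list was at 0.249 with no replicate block, and from 8.44e-05 to 0.0617 without each animal, lost without animal 1 (0.0617) and animal 6 (0.0504). The interferon list stayed past the threshold without each animal (3.78e-09 to 4.09e-07), as did the cholesterol list (1.72e-05 to 0.0164), and both did so with no replicate block, DESeq2 size factors, the stricter filter, halved counts and without animals 3 and 4. In that last run 3 lists turned direction: integrins and focal adhesion was higher (adjusted p = 0.00277), and oxidative phosphorylation (5.16e-04) and ribosomal proteins (0.0206) were lower. Further calls appeared for the ribosomal list without animal 2 (0.0418) and animal 5 (0.00311), for the extracellular matrix (0.0463) and mitochondrial (0.0362) lists without animal 5, for the erythroid list without animal 1 (0.0257) and animal 6 (0.0424), and for the steroid list without animals 3 and 4 (0.0468). The cause was not tested.

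The animal's share of variance was 73.7% with at least 1 CPM in 6 libraries, which removes low genes, 65.9% with a prior count of 0.5, and 65.9 to 69.1% without each animal; the treatment's share was then 6.75 to 8.08%, with fewer animals. Genes differing between animals numbered 2305 to 3541 without each animal. The larger likeness of EVs libraries kept its direction in 11 alternatives, but with a prior count of 0.5 or the stricter filter another split exceeded it, as without animal 2, 3, 4 or 6 and without animals 3 and 4 together. Over 50 named genes and 20 alternatives, 7 of 998 values changed sign without passing a threshold and 22 passed, 12 of them in DESeq2 with the animal as a block. Without 1 animal, uncalled log2 fold changes of some named genes moved by over 1.5 times from the value with all animals: CXCL8 (0.34 to 0.64), CASP8 (0.22 to 0.38), PLAT (0.32 to 0.64), UQCRQ (-0.22 to -0.10), RPL38 (0.07 to 0.24), ND2 (-1.17 to -0.37), CFTR (0.22 to 1.02), PECAM1 (0.30 to 0.56), ITGAM (-0.41 to -0.18), HAND1 (-0.94 to -0.37), GATA3 (-1.01 to -0.33), KRT8 (-0.17 to -0.02), KRT18 (-0.19 to 0.01) and CDX2 (-0.13 to 0.26). Others moved by less. Depth limits genes near the floor of 3 counts, 0.108 to 0.132 CPM.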

Other observations

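Outside the preset lists, DESeq2 with the animal as a block called genes that edgeR did not, and these were named after their values were seen. Higher with EVs in 6 of 6 animals were the interferon-induced gene ISG12(A) (59.1 ± 32.7 CPM in Control, 121.9 ± 70.3 CPM in EVs; DESeq2 adjusted p = 0.0190), the macrophage elastase gene MMP12 (15.3 ± 13.6 and 24.2 ± 18.3 CPM; adjusted p = 0.0190) and the natriuretic peptide gene NPPB (46.0 ± 27.1 and 72.1 ± 30.7 CPM; adjusted p = 0.0190). Lower in 6 of 6 were the secreted protease inhibitor gene FETUB (1227 ± 1680 and 424 ± 289 CPM; adjusted p = 0.00518), the angiotensin precursor gene AGT (DESeq2 log2 fold change -0.82, SE 0.22; adjusted p = 0.0409) and the epithelial serine protease gene PRSS8 (-0.44, SE 0.10; adjusted p = 0.0167). The Control library of animal 1 carried much of the FETUB mean, at 4576 CPM against 271 to 1236 CPM in the other Control libraries. Several split regroupings called as many genes in DESeq2, as given above.

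In animals 3 and 4 some genes differed between treatments by larger amounts than in the other animals; this was not tested. COL1A1, a fibrillar collagen gene, went from 3636 to 495 CPM in animal 3 and from 2345 to 514 CPM in animal 4, while the other 4 animals lay between 72.9 and 225 CPM in both groups. OVOL1 differed by -3.05 and -2.51 log2 units in these animals, and HAND1 by -2.20 and -1.73. The embryonic globin gene HBZ went from 6.51 to 14.9 CPM and from 5.85 to 17.7 CPM, and stood at 1.28 CPM or less in the other 8 libraries. IFNG stood at 93.9, 0.142, 3.42, 5.85, 56.1 and 155 CPM in the Control libraries of animals 1 to 6. The level of the interferon-response list was lowest in animal 1 (-1.31 log2 units from the mean of the animals) and highest in animal 5 (0.79).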
